A study of Mus musculus with 4 samples.

How the data were processed

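Messenger RNA was counted in single cells of mouse lung endothelium in 4 libraries, each from the lung of 1 mouse: control normoxia, control hypoxia, knockout normoxia and knockout hypoxia. Per the labels, lungs were digested, CD31-positive cells were enriched on magnetic beads, and live cells positive for CD31 and CD146 and negative for CD45, LYVE1, LY76, PDPN and EPCAM were sorted, frozen, thawed and made into 10x Chromium 3' libraries. The matrices hold raw UMI counts per gene and barcode, deposited as Cell Ranger wrote them, version 4.0.0 or 4 per the file headers, with no normalization. The submitters' notes name the build mm10 and state that Cell Ranger removed empty barcodes. The gene annotation the authors used was not given in the sources used here. For each library a matrix of called cells and a matrix of all barcodes were deposited. The other deposited files hold names of barcodes and features per the labels, not measurements. Cluster names of the authors were not used here, and classes were made anew.

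The matrices of called cells held 2920, 2212, 3647 and 1954 barcodes in the order control normoxia, control hypoxia, knockout normoxia, knockout hypoxia, where the series text speaks of about 2000 to 5000 cells processed per sample. Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept, which left 2447, 1824, 3031 and 1550. Doublets were scored per library with Scrublet in scanpy. Its automatic threshold marked 9, 9, 2 and 8 cells, below the expected 0.8% per 1000 barcodes, so the top-scoring 57, 32, 88 and 24 cells at the expected rate were removed. The remaining cells numbered 2390, 1792, 2943 and 1526, with 8921922, 6850439, 11081447 and 9103706 UMIs, median genes per cell of 1636, 1661, 1677 and 2271 and median mitochondrial shares of 4.17%, 3.83%, 4.17% and 4.33%.

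For clustering, counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen within libraries, each gene was centered within its library, and 30 principal components and 15 neighbors fed the Leiden method at resolution 1.0. Mitochondrial, ribosomal protein, hemoglobin and sex-linked genes were left out of the variable genes. Clusters were named after 19 marker lists. A name needed at least 3 markers of a class, and no more leading genes of another class than of its own among the 10 leading genes, each detected in at least 25% of the cluster. These naming thresholds were set after the clusters had been seen. Names end in "-like" because they rest on transcripts alone. Counts were summed per class and library and scaled to CPM (UMIs per 1000000 UMIs of the class). General capillary-like cells were the main population.

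With 1 mouse per group, cells are not replicates, so no test, p-value or standard error was computed. CPM carry exact Poisson 95% intervals, ratios exact conditional binomial intervals and shares exact Clopper-Pearson intervals, all of which cover counting error only. A gene counted as higher or lower when it had at least 20 CPM and 30 UMIs in the higher library and a ratio of at least 1.5 on the scale log2(CPM + 1). The comparisons were hypoxia against normoxia within each genotype, knockout against control within each oxygen level, and the difference of the hypoxia responses, with correlations across genes and 200 resamples of the counts. For 21 gene lists, the median log2 ratio of the measured members was placed among 10000 random lists of the same size drawn from 20 expression bins. Genes of a random list were drawn independently, whereas members of a gene list can vary together. A percentile therefore describes these libraries and does not measure how unusual a median is between mice.

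Genes were named by a fixed rule. In each comparison it took the 10 largest and 10 smallest ratios on the scale log2(CPM + 5) among genes that met the size rule with at least 50 CPM in the higher library and went the same way in at least 1 other vascular class with 100 cells in both libraries. For the difference of responses it took 5 in each direction. Markers of non-endothelial cells, hemoglobin, mitochondrially encoded, ribosomal protein and sex-linked genes and numbered gene models were left out of this ranking. Nfat5 and Pdgfb were always named, and up to 3 members of each gene list furthest in the direction of its median. Members of marker lists, the leading genes of clusters, genes with opposite responses and genes in droplets were named after their values were seen. All 213 named genes among 32285 features were matched by identifier to GENCODE M21 on GRCm38 for coordinates.

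Free RNA was measured in droplets of at most 100 UMIs outside the called barcodes, 452719, 308421, 442709 and 483506 in number, with 1663648, 1332769, 1438264 and 1546499 UMIs. From 22 surfactant, secretoglobin, hemoglobin and immunoglobulin genes, the share of free RNA in vascular cells was estimated at 2.22%, 3.32%, 2.69% and 1.45%. In knockout hypoxia, Igkc and Ighm held 192 and 37 UMIs in droplets and 0 in cells, which lowers that estimate. Free RNA was not subtracted in the main values.

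The size rule was tested on simulated data with 200 altered genes per comparison. The counts were Poisson draws from the pooled profile of both libraries, so they held counting error only. They had no variation between mice, cells or preparations, so the rates below do not cover such variation. Of unaltered genes the size rule called 16 of 6547 for hypoxia in control mice, 9 of 6612 for hypoxia in knockout mice, 8 of 6632 for the knockout in normoxia and 26 of 6510 for the knockout in hypoxia. In the same order it recovered 50.8%, 52.3%, 38.4% and 58.3% of genes set at 1.5-fold, the threshold itself, and 98.5%, 100%, 100% and 98.6% of genes set at 2-fold. All genes set at 4-fold were recovered (100% in each comparison). The intervals held the set ratio for 95.6%, 95.4%, 96.0% and 95.4% of genes.

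Before the data were examined, the comparisons, size rule, gene lists, marker lists, naming rule for genes and 23 entries of alternatives were fixed. These covered TMM factors (1.0204, 0.9778, 1.0284 and 0.9745), median-of-ratios size factors, totals without mitochondrial and ribosomal protein genes, a minimum of 5 or 100 CPM, no filter, a pseudocount of 10 CPM and equal weight per cell. They also covered filters of 200 genes with 20% and 1000 genes with 5% mitochondrial UMIs, no doublet removal, no centering, resolutions of 0.5 and 2.0, all vascular classes together, subtraction of free RNA, and cells thinned to 1 depth before clustering. Added after the data were seen were the class with cluster 8, without cluster 6 or without cluster 7, cluster 7 alone, clusters made without the genes that met the size rule, class shares under the filter of 200 genes with 20%, and counts thinned to the lowest total. A test of 1 more gene list, added after the data were seen, is not reported.

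Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for the TMM factors. The median-of-ratios factors followed the DESeq2 definition and were computed in Python.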

Results

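Messenger RNA was counted in single endothelial cells of mouse lung, in 4 groups of 1 mouse each. Control mice carried loxP-flanked Nfat5 alleles and received solvent. Knockout mice also carried a tamoxifen-activated Cre recombinase under the endothelial Cdh5 promoter and received 1 mg of tamoxifen per day for 5 days, so that endothelial cells lose Nfat5, which encodes a transcription factor of the osmotic stress response. Mice of each genotype were kept in normoxia or at 10% oxygen for 7 days. The control normoxia, control hypoxia, knockout normoxia and knockout hypoxia libraries gave 2390, 1792, 2943 and 1526 cells after filtering, with 8921922, 6850439, 11081447 and 9103706 UMIs (counted molecules). The median cell held 3210, 3350, 3274 and 5233 UMIs in the same order, so cells of the knockout hypoxia library were the deepest. With 1 mouse per group, no difference has a replicate check, no test was made, and each ratio compares 2 libraries rather than 2 conditions. Intervals are 95% intervals that cover counting error only.

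The cells were endothelial by their transcripts. The 8 pan-endothelial markers together reached 9963, 10060, 10310 and 9263 CPM (UMIs per 1000000 UMIs of the population) over all cells, in the order control normoxia, control hypoxia, knockout normoxia, knockout hypoxia, which is kept throughout. Markers of general capillary cells summed to 5089, 5707, 5565 and 5268 CPM, of aerocyte capillary cells to 2209, 1500, 1742 and 1289 CPM, of arterial cells to 1248, 1323, 1409 and 1300 CPM and of venous cells to 2762, 3652, 2521 and 2817 CPM. Lymphatic markers summed to 888, 792, 774 and 1062 CPM, of which Lyve1 gave 818, 611, 686 and 503 CPM, although LYVE1 protein was a negative gate of the sort. Non-endothelial lists stayed low. The highest was alveolar epithelium at 374, 296, 315 and 197 CPM, led by Hopx, followed by airway epithelium at 85.7, 67.4, 73.6 and 50.6 CPM, led by Tppp3. B cell markers lay between 37.1 and 52.2 CPM, nearly all Ebf1, pericyte and smooth muscle markers between 27.4 and 65.2 CPM, and monocyte and macrophage markers at most 32.2 CPM. Fibroblast markers reached at most 19.2 CPM, NK cell markers 22.6 CPM, neutrophil markers 7.49 CPM, erythroid markers 5.40 CPM, platelet markers 4.50 CPM, T cell markers 4.04 CPM and mesothelial markers 0.451 CPM. Cycling markers stood at 33.7, 179, 19.8 and 948 CPM. Y-linked Ddx3y was seen in all libraries, at 125, 114, 134 and 84.4 CPM, and Xist gave at most 3 UMIs in any library.

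General capillary-like cells, the most numerous class of the lung endothelium here, carried the main comparisons, with 1338, 1010, 1703 and 696 cells and 3865526, 3223359, 5176189 and 3395230 UMIs. The class joined 6 clusters that were held unequally by the libraries. Cluster 7, led by Depp1, Ntrk2, Tiam1 and Sparcl1, held 8, 99, 6 and 590 cells, so it made up most of the class in the knockout hypoxia library, while clusters 3, 4 and 5 together with cluster 9 held most of it in the other libraries. This split of the hypoxia libraries depended on centering genes within libraries. Without centering, a cluster led by Peg3, Ntrk2 and Sparcl1 held 10, 1140, 10 and 724 cells. Cluster 6, led by the interferon-induced genes Ifit3, Ifit1 and Isg15, held 148, 240, 204 and 44 cells.

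The targeted gene, Nfat5 (ENSMUSG00000003847, GRCm38 chromosome 8, 107293470 to 107379517), stood at 299 CPM in control normoxia, 226 CPM in control hypoxia, 298 CPM in knockout normoxia and 179 CPM in knockout hypoxia. Knockout over control gave a ratio of 0.997 (0.923 to 1.08) in normoxia and 0.791 (0.709 to 0.882) in hypoxia. The libraries count tags near the 3' end of transcripts, where the last annotated exon ends at 107379516, whereas annotated exon 4 spans 107338809 to 107339367. The tags therefore do not check the deletion of exon 4 or the genotype labels. Pdgfb (ENSMUSG00000000489), an endothelial growth factor that recruits mural cells and was named in advance, stood at 261, 490, 366 and 498 CPM. Hypoxia over normoxia gave 1.88 (1.73 to 2.03) for Pdgfb in control mice and 1.36 (1.28 to 1.46) in knockout mice.

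The first comparison asked what 7 days of 10% oxygen did to lung capillary cells with intact Nfat5. The medians of HIF target (hypoxia-inducible factor), glycolysis and extracellular matrix genes were above 0 in the control hypoxia library, beyond all random lists, and Plvap of fenestral diaphragms was among the genes furthest below normoxia. Among 6931 genes with at least 20 CPM and 30 UMIs in the higher library, 525 were at least 1.5-fold higher and 563 at least 1.5-fold lower on the scale log2(CPM + 1), of which 205 and 159 were at least 2-fold apart. Higher genes made up 48.2% of these calls, but 655 against 447 (59.4%) with median-of-ratios size factors, so the balance of directions depended on scaling.

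Peg3, an imprinted zinc finger gene (ENSMUSG00000002265, chromosome 7, 6703892 to 6730431), stood apart most in control hypoxia, at 791 CPM against 16.3 CPM, a ratio of 48.5 (37.8 to 63.3). Ntrk2, the receptor for brain-derived neurotrophic factor, was at 737 against 20.4 CPM (ratio 36.1, 28.8 to 45.7), and Ankrd37, a known HIF target, at 495 against 15.8 CPM (31.4, 24.3 to 41.2). Sparcl1, a matricellular protein gene, was at 1633 against 78.4 CPM, and Depp1, a FOXO-regulated gene, at 239 against 9.31 CPM. Cdk19, a kinase of the Mediator complex, was 9.46-fold higher, Amd1 of polyamine synthesis 8.98-fold, the mitophagy receptor gene Bnip3 9.43-fold, and Pde4b, which breaks down cyclic AMP, 7.59-fold. The receptor phosphatase gene Ptprr was at 75.4 against 4.14 CPM, but its log2 ratio of 3.89 was 2.59 over all vascular classes together. Among lower genes, Slc16a9, a transporter of the monocarboxylate family, was at 39.4 against 231 CPM, and Insig1, which restrains sterol synthesis, at 9.93 against 54.1 CPM. Plvap (ENSMUSG00000034845), which forms the diaphragms of fenestrae and caveolae, was at 328.5 against 1312 CPM (ratio 0.2504, 0.234 to 0.268). The cytochrome P450 gene Cyp4b1 was at 151 against 797 CPM. Over all vascular classes the log2 ratios of Plvap and Cyp4b1 moved from -1.99 and -2.39 to -1.06 and -1.61, and those of Peg3 and Pde4b from 5.52 and 2.92 to 4.84 and 2.30. The apelin receptor gene Aplnr was at 54.9 against 194 CPM and Npr3, the clearance receptor of natriuretic peptides, at 94.6 against 318 CPM. Ankrd44, Neurl3, Plxna1 and Gng2 had ratios of 0.262, 0.257, 0.273 and 0.260, and the log2 ratio of Plxna1 was -1.84 in the class but -1.08 over all vascular classes.

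Of 20 measured HIF target genes, 12 were higher and 0 lower in control hypoxia, with a median log2 ratio of 1.14 (1.89 at 100 CPM or more), above all of 10000 random lists matched on expression (percentile 100). P4ha1, a collagen prolyl hydroxylase gene, was at 114 against 21.5 CPM. Glycolysis had 8 of 12 genes higher (median 0.87, percentile 100), with Ldha at 495 against 134 CPM and Pfkl at 167 against 37.3 CPM. Extracellular matrix had 7 of 11 genes higher and 1 lower (median 0.98, percentile 100), among them Timp3 at 707 against 143 CPM. The interferon response had 8 of 22 genes higher and 2 lower (median 0.34, percentile 99.98), with Ifit3 at 173 against 68.6 CPM, and this median was -0.03 without cluster 6. Vasoactive and PDGF genes had 6 of 13 higher and 1 lower (median 0.21, percentile 97.6), including Edn1, which encodes endothelin, at 962 against 157 CPM (6.14, 5.62 to 6.70) and Nos3 at 89.4 against 30.3 CPM. This median was -0.02 over all vascular classes. The circadian clock list had 2 of 7 genes higher and 1 lower (median 0.53, percentile 99.9), with Cry1 at 35.1 against 7.24 CPM. NFAT5 osmotic targets had 3 of 9 higher and 1 lower (median 0.25, percentile 96.4; 1.98 at 100 CPM or more). Those 3 included the near-identical heat shock genes Hspa1a, at 1695 against 303 CPM, and Hspa1b, at 1098 against 246 CPM, whose tags may be shared in counting, and the taurine transporter gene Slc6a6, at 730.3 against 185 CPM.

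Immediate early and heat shock genes had 8 of 22 higher and 2 lower (median 0.03, percentile 79.3), with the flow-responsive Klf2 at 2656 against 958 CPM. The VEGF, Notch and angiopoietin list had 4 of 18 higher and 3 lower (median 0.08, percentile 90.0), with Vegfc at 249.7 against 70.4 CPM. BMP and TGF-beta genes had 4 of 15 higher and 3 lower (median 0.08, percentile 86.8), with Smad7 at 853 against 418 CPM. The unfolded protein list had 1 of 13 higher (median 0.20, percentile 97.52), with Herpud1 at 161 against 101 CPM. Antigen presentation had 6 of 18 higher (median -0.06, percentile 37.8) and endothelial identity 5 of 20 higher and 1 lower (median -0.01, percentile 62.5). Both medians were above 0 with TMM or median-of-ratios scaling, and the means of both lists were above 0 (0.35 and 0.21). Erg, a transcription factor of endothelial identity, was at 80.0 against 136 CPM. Nuclear oxidative phosphorylation genes had 1 of 78 lower (median -0.23, percentile 0.01), namely Ndufa4 at 331 against 511 CPM. The 13 mitochondrially encoded mRNAs had 1 lower (median -0.22, percentile 3.05), mt-Nd4l at 614 against 927 CPM. None of 82 ribosomal protein genes met the rule (median -0.02, percentile 58.8), and that median was 0.04 and 0.05 with TMM and median-of-ratios scaling. Fatty acid genes had 2 of 19 higher and 3 lower (median -0.12, percentile 23.3), with the fatty acid translocase gene Cd36 at 1244 against 2747 CPM. The cell cycle list had 2 of 6 lower (median -0.55, percentile 0.24), but the clusters led by cell cycle genes lie outside the class, and over all cells 3 of 10 were higher and 0 lower. The list of NRF2 and antioxidant genes had 1 of 12 lower (median -0.30, percentile 1.21; 0.03 with no filter on low counts), and inflammation genes 4 of 11 higher and 2 lower (median -0.18, mean 0.10, percentile 11.4; median 0.83 at 100 CPM or more). Cx3cl1, a leukocyte-attracting chemokine, was at 15.5 against 47.6 CPM. None of 4 sex-linked genes met the rule (median -0.15).

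**Figure D1:**
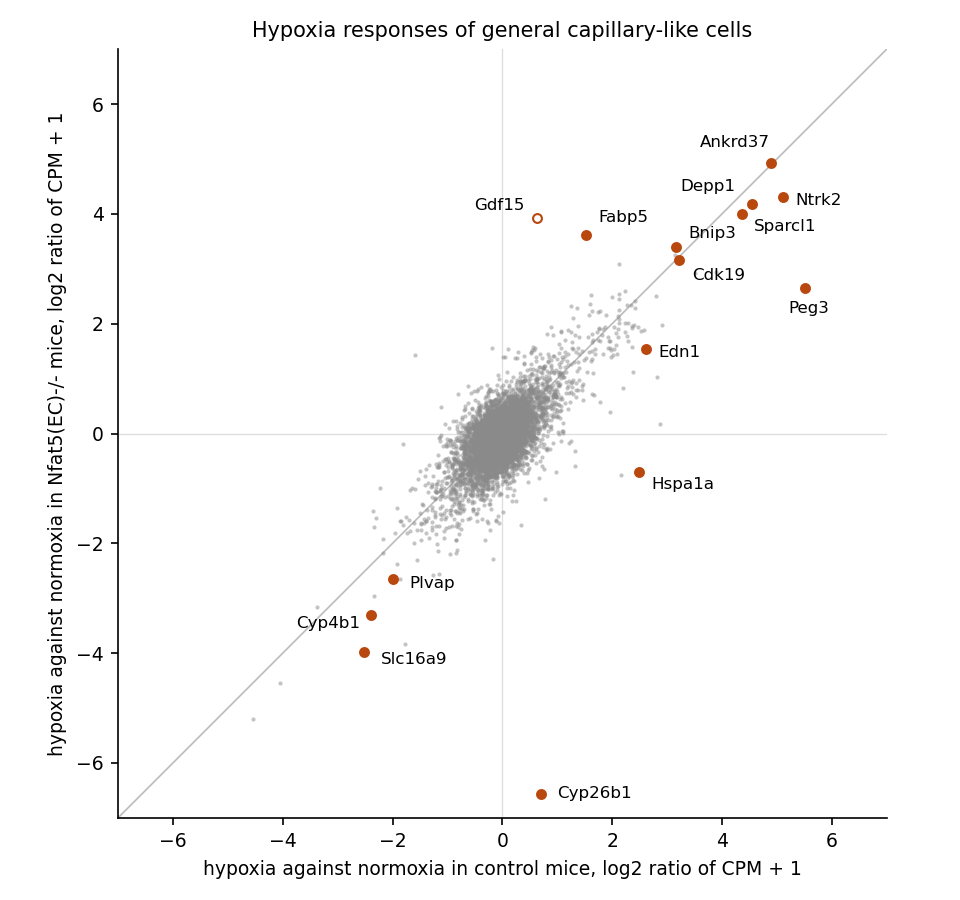
Each point is 1 gene with at least 20 CPM and 30 UMIs in both comparisons of general capillary-like cells, with the hypoxia over normoxia log2 ratio in control mice on the x axis and in knockout mice on the y axis; the grey diagonal marks equal ratios and the open point (Gdf15) did not meet the minimum in control mice. Ankrd37 and Bnip3 lie near the diagonal, Ntrk2 lies under it, and Cyp26b1, Hspa1a and Peg3 lie far under it.

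The second comparison asked the same of mice whose endothelial cells should lack Nfat5. The HIF target median was again above 0, all measured glycolysis genes met the size rule, and the median of BMP and TGF-beta genes was below 0. Of 7063 genes, 645 were higher and 821 lower (252 and 274 at least 2-fold). Higher genes made up 44.0% of these calls, but 797 against 660 (54.7%) with TMM factors and 841 against 623 (57.5%) with median-of-ratios size factors. Most knockout hypoxia cells of the class were in cluster 7 and most knockout normoxia cells in clusters 3 and 4.

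Ankrd37 was at 462 against 14.3 CPM (ratio 32.3, 25.6 to 41.4), Ntrk2 at 745 against 36.5 CPM (20.4, 17.6 to 23.8) and Sparcl1 at 1373 against 84.8 CPM (16.2, 14.7 to 17.9). Bnip3 was 11.2-fold higher, Amd1 9.76-fold, Cdk19 9.11-fold, Depp1 18.9-fold and Tiam1, an activator of the GTPase Rac, 8.95-fold. Fabp5, a fatty acid binding protein gene, was at 137 against 10.2 CPM (13.4, 10.1 to 18.2). Gdf15 (ENSMUSG00000038508), a stress-induced cytokine gene of the TGF-beta family, was at 61.0 against 3.09 CPM, and its log2 ratio of 3.92 was 1.91 over all vascular classes and 4.85 without cluster 7. The gene furthest below normoxia was Cyp26b1 (ENSMUSG00000063415, chromosome 6, 84571414 to 84593908), which encodes an enzyme that degrades retinoic acid, at 19.4 against 1929 CPM, or 99.2-fold lower. Dhrs3, a retinaldehyde reductase gene, was at 12.4 against 189 CPM. Slc16a9 was at 12.7 against 214 CPM, Cyp4b1 at 82.8 against 828 CPM and Plvap at 199 against 1260 CPM. Over all vascular classes many of these log2 ratios were closer to 0, at 2.84 in place of 3.62 for Fabp5, 3.37 in place of 4.19 for Depp1 and 3.36 in place of 4.00 for Sparcl1, and at 2.64 and 2.56 in place of 3.26 and 3.17 for Amd1 and Cdk19. There Cyp26b1 was at -5.84 in place of -6.56, Plvap and Cyp4b1 at -1.43 and -1.99 in place of -2.65 and -3.31, Dhrs3 at -3.02 in place of -3.83 and Slc16a9 at -2.96 in place of -3.97 (-5.45 without cluster 7). The leukemia inhibitory factor receptor gene Lifr was at 114 against 518 CPM, Ptpru at 25.3 against 127 CPM and Hs3st1, which sulfates heparan chains, at 44.2 against 195 CPM (log2 -2.12, but -1.28 over all vascular classes). Ankrd44 and Gng2 had ratios of 0.192 and 0.148.

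Of 21 measured HIF target genes, 15 were higher and 0 lower in knockout hypoxia (median 1.22, percentile 100; 2.04 at 100 CPM or more), with the glucose transporter gene Slc2a1 at 56.8 against 9.08 CPM. All 12 glycolysis genes were higher (median 1.37, percentile 100), including Ldha at 542 against 141 CPM and Aldoa at 748 against 229.5 CPM. Extracellular matrix had 8 of 11 genes higher (median 1.24, percentile 100), with Fbln2 at 45.4 against 6.96 CPM. The circadian list had 4 of 8 higher (median 0.69, percentile 99.9), with Per1 at 131 against 45.0 CPM, although its median was -0.10 without cluster 7. Ribosomal protein genes had 10 of 82 higher (median 0.40, percentile 99.99), with Rpl10a at 571 against 344 CPM. Nuclear oxidative phosphorylation had 3 of 78 higher (median 0.18, percentile 99.9), with Atp5e at 437 against 289 CPM. The unfolded protein and amino acid list had 2 of 15 higher and 1 lower (median 0.32, percentile 97.1), with the asparagine synthetase gene Asns at 29.8 against 9.27 CPM. BMP and TGF-beta genes had 7 of 14 lower and 2 higher (median -0.47, percentile 0.1). Bmpr2, a BMP receptor whose human gene is mutated in pulmonary arterial hypertension, was at 722 against 1789 CPM (0.404, 0.386 to 0.422), and Eng, a coreceptor, at 558 against 1212 CPM.

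NFAT5 osmotic targets had 3 of 9 lower and 1 higher (median -0.23, percentile 9.93). The 3 were Hspa1a at 969 against 1576 CPM, Hspa1b at 596 against 1007 CPM and Akr1b3, which encodes aldose reductase, at 63.3 against 101 CPM. Vasoactive and PDGF genes had 5 of 15 higher and 5 lower (median 0.00, percentile 49.3), with Edn1 at 708 against 242 CPM and Apln at 34.5 against 4.64 CPM. The VEGF, Notch and angiopoietin list had 4 of 18 higher and 5 lower (median -0.09, percentile 20.9, 0.04 with median-of-ratios scaling), with Angpt2, an antagonist of the Tie receptor, at 2.65 against 27.4 CPM. Interferon genes had 1 of 22 higher and 3 lower (median -0.16, percentile 7.10), with Iigp1 at 427 against 1081 CPM. Their median was 0.51 without cluster 7, when cluster 6, led by interferon-induced genes, held the most knockout hypoxia cells left in the class. Antigen presentation had 5 of 18 higher (median 0.00, percentile 32.1), with the class II genes Cd74 at 2524 against 829.6 CPM and H2-Ab1 at 1064 against 487 CPM. Fatty acid genes had 2 of 20 higher and 4 lower (median -0.23, percentile 5.32), with Cd36 at 1146 against 2620 CPM. The cell cycle list had 1 of 7 higher and 1 lower (median 0.31, percentile 92.9; 1.10 at the lower clustering resolution), and inflammation genes 4 of 12 higher and 4 lower (median -0.11, percentile 24.5; 0.65 at 100 CPM or more). Endothelial identity had 6 of 20 higher and 1 lower (median -0.02, percentile 25.8), and immediate early and heat shock genes 4 of 22 higher (median -0.03, percentile 17.3). None of the 13 mitochondrially encoded mRNAs met the rule (median -0.05, percentile 21.2). These last 3 medians were above 0 with TMM or median-of-ratios scaling, and the means of the identity, immediate early and inflammation lists were above 0 (0.13, 0.05 and 0.01). Of NRF2 genes 0 of 12 met the rule (median 0.01, mean -0.02, percentile 57.9), and 2 of 4 sex-linked genes were lower (median -0.57).

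The third comparison set the hypoxia responses of both genotypes side by side. Across 6712 genes measured in both, the log2 ratios had a Pearson correlation of 0.711 (0.704 to 0.717, over resampled counts) and a Spearman correlation of 0.550. Genes are not independent replicates, and the 2 responses share no library. Of 490 genes higher in control hypoxia, 311 were also higher in knockout hypoxia, where independent lists would share 41.2. Of 528 genes lower in control hypoxia, 296 were also lower in knockout hypoxia (independent lists 58.5). Opposite calls were made for 9 genes higher only in control hypoxia and lower in knockout hypoxia, and for 3 genes the other way round, where independent lists would share 54.2 and 44.4.

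The difference of the responses, knockout minus control, was at least 1.5-fold higher for 454 and lower for 576 of 7282 genes. Among genes with at least 50 CPM in a library, the level set for naming single genes, it was highest for Gdf15 (log2 3.30), Fabp5 (2.10), the microtubule-associated protein gene Map1b (1.85), the nuclear lamin gene Lmna (1.38) and Gask1b (1.35). Lmna was at 188, 189, 131 and 346 CPM. It was lowest for Cyp26b1 (-7.26), Hspa1a (-3.18), Hspa1b (-2.91), Peg3 (-2.86) and the chaperone gene Hsph1 (-2.70). Over all vascular classes the values for Gdf15, Map1b and Cyp26b1 were 1.54, 0.54 and -6.52. That for Gdf15 was 4.67 without cluster 6 and 4.10 without cluster 7.

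The next comparison asked what loss of endothelial Nfat5, together with the tamoxifen that induced it, went with in normoxia. Few genes were apart, and Cyp26b1 and heat shock genes were the furthest above control. Of 6883 genes, 114 were higher and 36 lower in the knockout library, and 18 and 4 were at least 2-fold apart. Higher genes made up 76.0% of these calls, against 87 higher and 46 lower (65.4%) with median-of-ratios size factors. Genotype and tamoxifen treatment differed together between these libraries, so the comparison does not separate them.

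Cyp26b1 was at 1929 CPM in knockout normoxia against 47.1 CPM in control normoxia, a ratio of 40.97 (35.4 to 47.7). It was at 2728 against 176 CPM in arterial-like and 1134 against 30.9 CPM in venous-like cells. A UMI of Cyp26b1 was seen in 90.9% of 1703 general capillary-like cells of knockout normoxia, whose median depth was 2908 UMIs, but in 21 of 200 aerocyte-like cells at a median depth of 6618 UMIs. Aerocyte-like cells held it at 29.7 CPM in knockout normoxia and in 0 of 226 cells in control normoxia. Droplets without cells of the knockout normoxia library held it at 1043 CPM, so free RNA can reach the aerocyte-like level. Dhrs3, of the same retinoid pathway, was at 189 against 78.9 CPM (2.40, 2.10 to 2.73). Hspa1a was at 1576 against 303 CPM (5.21, 4.90 to 5.54) and Hspa1b at 1007 against 246 CPM. The small heat shock protein gene Hspb1 was at 469 against 208 CPM. The cell cycle kinase gene Cdk6 was at 202 against 81.0 CPM, the phosphatase gene Ptpru at 127 against 52.8 CPM and the zinc finger gene Glis2 at 71.5 against 34.7 CPM. Bcl7a, which encodes a subunit of a chromatin remodeler, and Nos1ap, an adaptor of nitric oxide synthase, had ratios of 2.07 and 2.02. The naming rule left 7 lower genes. Gmfg, which encodes an actin regulator, was at 84.8 against 171 CPM (0.495, 0.438 to 0.560), the atypical chemokine receptor gene Gpr182 at 121 against 197 CPM, and the junctional protocadherin gene Pcdh12 at 37.7 against 61.3 CPM. Ptms, Sap30l, Pabpn1, a nuclear poly(A) binding protein gene, and Xpo1, a nuclear export receptor gene, had ratios of 0.644, 0.629, 0.652 and 0.649.

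NFAT5 osmotic targets had 5 of 9 genes higher and 0 lower in knockout normoxia (median 0.60, percentile 100). Beside Hspa1a and Hspa1b they included the cationic amino acid transporter gene Slc7a1, at 29.9 against 17.3 CPM. Immediate early and heat shock genes had 4 of 22 higher (median 0.16, percentile 100), with Hsph1 at 47.0 against 8.02 CPM and Hsp90aa1 at 725 against 424 CPM. Nuclear oxidative phosphorylation had 0 of 78 past the rule, with a median of -0.15 under all random lists (percentile 0). Ribosomal protein genes had 0 of 82 (median -0.08, percentile 2.18) and the cell cycle list 0 of 6 (median -0.24, percentile 0.19). BMP and TGF-beta genes had 0 of 14 (median 0.09, percentile 97.4), the unfolded protein list 0 of 13 (median -0.12, percentile 2.99) and fatty acid genes 0 of 19 (median -0.09, percentile 4.12). Vasoactive and PDGF genes had 1 of 13 higher (median 0.05, percentile 90.1), Edn1 at 242 against 157 CPM, while Pdgfb was at 366 against 261 CPM. Inflammation genes had 1 of 12 higher (median 0.06, percentile 89.3), the adhesion molecule gene Vcam1 at 22.6 against 6.73 CPM. HIF target genes had 1 of 16 higher (median 0.07, percentile 82.9), the circadian repressor gene Bhlhe40 at 54.5 against 36.0 CPM. Interferon genes had 1 of 21 higher (median -0.06, percentile 12.8). No member passed the rule among 12 glycolysis genes (median -0.05, percentile 23.6), 13 mitochondrially encoded mRNAs (-0.07, percentile 34.4), 17 VEGF, Notch and angiopoietin genes (-0.02, percentile 52.3) or 18 antigen presentation genes (-0.05, percentile 39.5). The same held for 20 endothelial identity genes (-0.04, percentile 44.0), 10 matrix genes (-0.00, mean 0.10, percentile 57.9), 5 clock genes (-0.06, percentile 26.5), 12 NRF2 genes (-0.04, percentile 27.9) and 4 sex-linked genes (0.14). Jag1, a Notch ligand, was at 50.4 against 75.8 CPM, and Gpx1, which encodes a glutathione peroxidase, at 64.5 against 95.2 CPM.

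The last comparison asked how hypoxic capillary cells of the 2 genotypes differed. The medians of interferon and of BMP and TGF-beta genes were below 0, and those of ribosomal protein, oxidative phosphorylation and matrix genes above 0. Most members of these lists did not meet the size rule. The interferon median turned when cluster 6, which interferon genes lead, or cluster 7 was left out. It was below 0 in the other vascular classes. Of 6828 genes, 233 were higher and 248 lower (40 and 27 at least 2-fold). Higher genes made up 48.4% of these calls, against 319 higher and 226 lower (58.5%) when mitochondrial and ribosomal protein genes were left out of the total. Most of the class was in cluster 7 in the knockout library (590 of 696 cells) and in the other clusters in the control library (99 of 1010 cells in cluster 7). Within cluster 7 alone, 601 genes were higher and 203 lower, and without cluster 7, 310 were higher and 657 lower. A gene reaches the UMI minimum more easily when it is higher in the library with more cells. That was the knockout library within cluster 7 and the control library without it, so these counts cannot tell whether the balance turned with the clusters. The median of compared genes was 0.11 within cluster 7 and -0.09 without it. Within cluster 7 it was -0.04 over the 1898 genes with a mean of at least 100 CPM.

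Gdf15 was at 61.0 CPM in knockout hypoxia against 6.52 CPM in control hypoxia (9.36, 5.96 to 15.4), and its log2 ratio of 3.04 was 1.42 over all vascular classes. That ratio was 2.10 with the larger pseudocount, 4.35 without cluster 6, 4.07 within cluster 7 and 3.84 without cluster 7. Fabp5 was at 137 against 39.1 CPM (3.51, 2.88 to 4.31), Map1b at 54.8 against 17.7 CPM and Neurl3, a ubiquitin ligase gene, at 69.8 against 26.4 CPM. The log2 ratio of Map1b was 1.58 in the class and 0.64 over all vascular classes, and that of Neurl3 1.37 in the class and 2.47 within cluster 7. Gask1b was at 129 against 44.7 CPM, the tetraspanin gene Cd81 at 476 against 216 CPM and Phlda3, a target of p53, at 181 against 81.0 CPM. Within cluster 7 alone the log2 ratios of Fabp5, Gask1b, Cd81 and Phlda3 were 1.20, 0.31, 0.11 and 0.26, where the whole class gave 1.79, 1.51, 1.13 and 1.15, and Phlda3 was at 0.46 over all vascular classes. The cell cycle regulator gene Rgcc was at 181 against 75.4 CPM, and Cnn2 and Marcksl1, of the actin cytoskeleton, had ratios of 2.34 and 2.37. Peg3 was at 115 against 791 CPM (0.146, 0.131 to 0.162) and Cyp26b1 at 19.4 against 77.3 CPM (0.252, 0.189 to 0.331), with log2 -1.94 for Cyp26b1 in the class and -1.12 within cluster 7. Lpl, which encodes lipoprotein lipase, was at 239 against 669 CPM (0.357, 0.329 to 0.387), with a log2 ratio of -1.48 in the class and -0.73 within cluster 7. Vwf, which encodes von Willebrand factor, was at 373 against 979 CPM and the prostaglandin synthase gene Ptgs1 at 25.9 against 72.0 CPM, but their log2 ratios over all vascular classes were -0.29 and -0.16. The log2 ratio of Ptgs1 was -1.44 in the class, -2.14 within cluster 7 and -0.40 without cluster 7. Hs3st1 was at 44.2 against 118 CPM, with log2 -1.40 in the class and -0.75 over all vascular classes. Ifit3 was at 58.9 against 173 CPM, Ifit1 at 86.3 against 224 CPM, Ifit3b at 16.5 against 52.1 CPM and Ifi213 at 21.8 against 60.2 CPM. Without cluster 6 the log2 ratio of Ifit3 was 0.09 in place of -1.53, that of Ifit1 was -0.32 in place of -1.37 and that of Ifit3b -0.74 in place of -1.60. Without cluster 7, when cluster 6 was the largest left in knockout hypoxia, those of Ifit3, Ifit1 and Ifit3b were 0.23, -0.06 and -0.10. That of Ifi213 was -0.66 within cluster 7 in place of -1.42. Ifit3 and Ifit3b are close paralogs that may share tags.

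The interferon response had 8 of 23 genes lower and 1 higher in knockout hypoxia (median -0.52, percentile 0). This median was 0.02 without cluster 6 and 0.09 without cluster 7, while clusters made without the differing genes gave -0.47. Leaving out cluster 6 or 7 changes the weight of cluster 6, which interferon genes lead, so neither value can settle the direction. In aerocyte-like, arterial-like and venous-like cells, which lie outside these clusters, the median was -0.95 (15 of 19 lower), -0.18 and -0.20. BMP and TGF-beta genes had 4 of 15 lower (median -0.39, percentile 0), with the BMP target genes Id1 at 489 against 793 CPM and Id3 at 449 against 858 CPM. Ribosomal protein genes had 4 of 82 higher (median 0.33, percentile 100), with Rps28 at 972 against 618 CPM. Nuclear oxidative phosphorylation had 2 of 78 higher (median 0.26, percentile 100), with Ndufc1 at 172 against 106 CPM. Glycolysis had 1 of 12 higher (median 0.41, percentile 100), Pgk1 at 96.3 against 60.8 CPM. Extracellular matrix had 4 of 11 higher (median 0.30, percentile 99.1), with Sparc at 1351 against 809 CPM. The cell cycle list had 1 of 7 higher (median 0.44, percentile 99.9), and that median was 1.24 at the lower clustering resolution. HIF target genes had 3 of 21 higher (median 0.08, percentile 82.4), with Bhlhe40 at 245 against 136 CPM. NFAT5 osmotic targets had 1 of 9 higher and 2 lower (median -0.22, percentile 2.71), the 2 being Hspa1a at 969 against 1695 CPM and Hspa1b at 596 against 1098 CPM. Vasoactive and PDGF genes had 1 of 14 higher and 1 lower (median -0.17, percentile 2.34), with Ramp2, an adrenomedullin coreceptor gene, at 1413 against 2116 CPM. Edn1 was at 708 against 962 CPM and Pdgfb at 498 against 490 CPM, which gave 1.02 (0.948 to 1.09), so no difference in Pdgfb was detectable at this depth. The VEGF, Notch and angiopoietin list had 2 of 17 lower (median -0.13, percentile 4.28), Hey1 at 52.7 against 87.2 CPM and the VEGF receptor gene Flt1 at 1319 against 2030 CPM.

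Antigen presentation had 2 of 18 lower in knockout hypoxia (median -0.03, percentile 23.7), including Nlrc5, a regulator of class I genes, at 28.9 against 55.2 CPM. Endothelial identity had 1 of 20 higher and 2 lower (median -0.07, percentile 10.1), with Ly6c1 at 1418 against 2234 CPM. Fatty acid genes had 1 of 18 higher and 2 lower (median -0.05, percentile 21.8), the 2 being Lpl and Cpt1a. Immediate early and heat shock genes had 2 of 22 higher and 2 lower (median -0.00, percentile 28.5), with Klf2 at 1681 against 2656 CPM. Inflammation genes had 2 of 10 higher and 1 lower (median -0.01, mean 0.09, percentile 36.2) and the unfolded protein list 1 of 15 higher and 1 lower (median -0.00, mean 0.07, percentile 34.3). The medians of antigen presentation, immediate early, inflammation and unfolded protein genes were above 0 when mitochondrial and ribosomal protein genes were left out of the total. The clock list had 1 of 8 higher and 1 lower (median 0.10, percentile 71.3), with Nr1d2 at 23.9 against 10.2 CPM. None of 13 mitochondrially encoded mRNAs (median 0.16, percentile 80.8), 12 NRF2 genes (0.19, percentile 96.6) or 4 sex-linked genes (-0.22) met the rule. Across 6429 genes measured in both, the knockout over control log2 ratios in normoxia and in hypoxia had a Pearson correlation of -0.10 and a Spearman correlation of -0.12. Of 92 genes higher in knockout normoxia, 12 were also higher in knockout hypoxia (independent lists 2.46), and 1 of 22 lower genes was lower in both (independent lists 0.726). Opposite calls were more numerous, with 11 genes higher in knockout normoxia and lower in knockout hypoxia (independent lists 3.03) and 5 the other way round (independent lists 0.589).

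**Figure D2:**
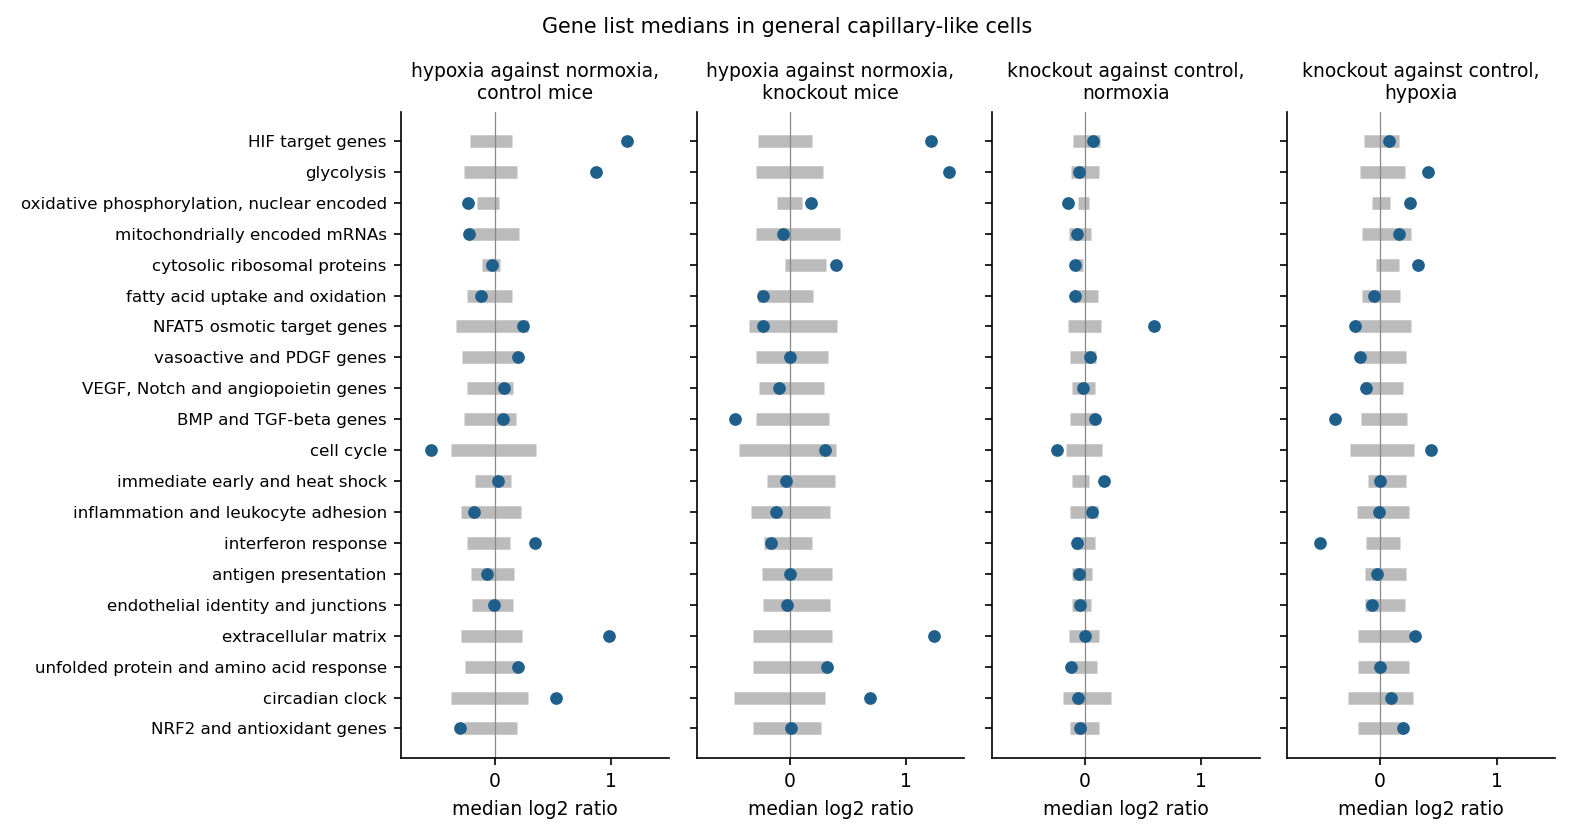
Blue points give the median log2 ratio of each gene list in general capillary-like cells for the 4 comparisons, and grey bars span 95% of 10000 random lists of the same size matched on expression. HIF target, glycolysis and matrix genes stand highest in both hypoxia comparisons, while the interferon median in the last panel (-0.52) was 0.02 without cluster 6, which interferon genes lead. Medians near 0 change sign under other scalings.

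**Figure D3:**
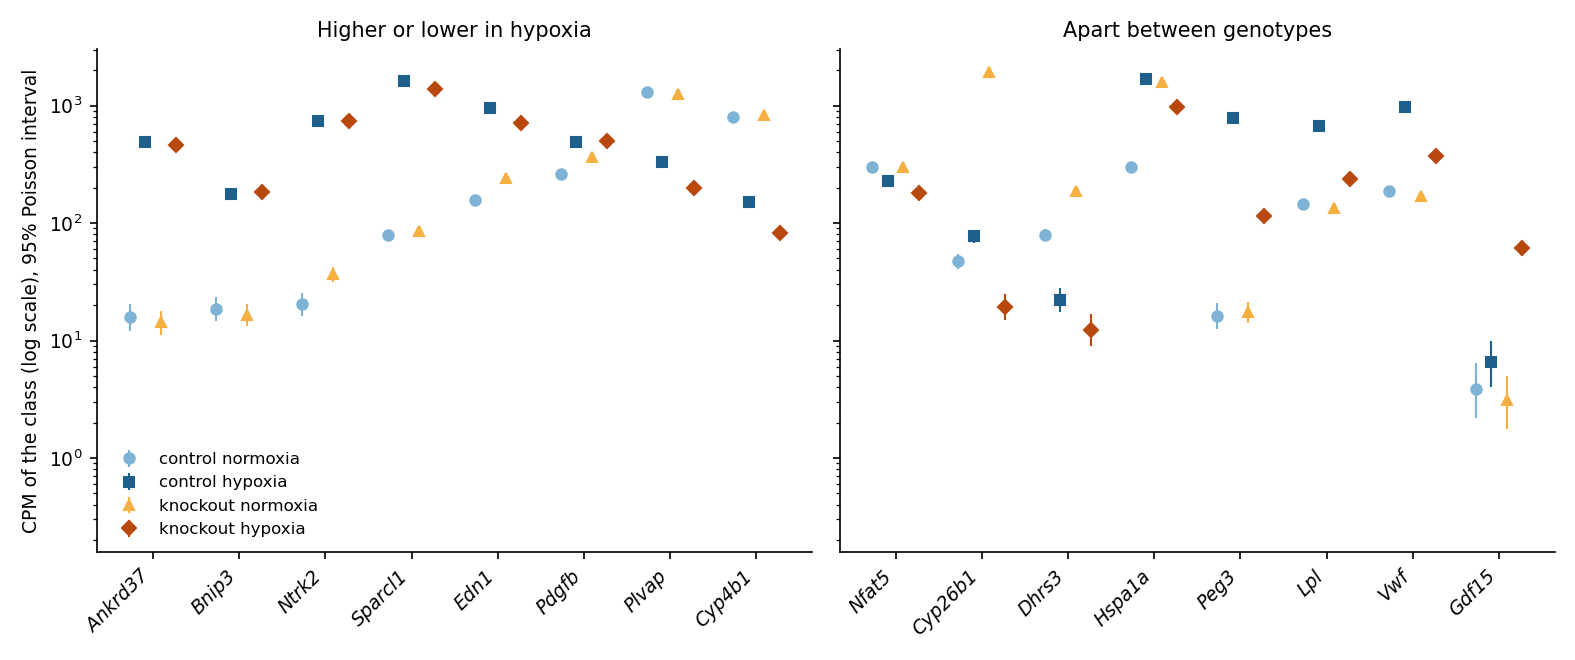
CPM (log axis) of 16 named genes in general capillary-like cells of the 4 libraries, 1 mouse each, with 95% Poisson intervals. Cyp26b1 stands at 1929 CPM in knockout normoxia and under 100 CPM in the other libraries, and Peg3 at 791 CPM in control hypoxia.

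Cells in division set the knockout hypoxia library apart. Over all cells, 22 of 23 measured cell cycle genes were higher in knockout hypoxia than in control hypoxia (median log2 ratio 2.00) and 22 of 23 higher than in knockout normoxia (median 3.91). Hypoxia over normoxia in control mice gave 3 of 10 higher (median -0.00), and knockout over control in normoxia gave 0 of 7 (median -0.17). More members met the minimum where the knockout hypoxia library entered, so these medians cover different genes and are not comparable. The 8 cycling markers summed to 33.7 CPM in control normoxia and 179 CPM in control hypoxia. Mki67, a marker of proliferating cells, was at 6.28, 45.0, 4.69 and 213 CPM, against 9.02, 12.8, 10.4 and 94.4 CPM in droplets without cells. To compare shares of cells, clusters were made again after leaving out 5679 genes that differed by the size rule, a step added after the data had been seen. Cycling-like cells then were 3 of 2390 (0.126%), 18 of 1792 (1.00%, 0.596 to 1.58), 5 of 2943 (0.170%) and 143 of 1526 cells (9.37%, 7.96 to 10.9, exact Clopper-Pearson). General capillary-like cells were 69.5%, 70.5%, 74.1% and 58.1% of cells, aerocyte-like cells 9.33%, 10.1%, 6.73% and 9.76%, arterial-like cells 6.23%, 5.30%, 6.08% and 6.36% and venous-like cells 14.7%, 12.8%, 12.8% and 15.01%. Lymphatic-like cells, which the sort gated against by LYVE1 and PDPN, were 0.0837%, 0.279%, 0.136% and 1.38%, but 0.418%, 0.837%, 0.816% and 3.87% in the main clustering and up to 5.57% in knockout hypoxia with the filter of 200 genes and 20% mitochondrial UMIs. The sort and the bead enrichment can set such shares. The lymphatic-like cluster of the main clustering held 108 cells at a median of 1605 UMIs. At resolutions 0.5 and 2.0 it held 32 cells at a median of 6518 UMIs. At resolution 2.0 an unnamed cluster of 78 cells had a median of 1141 UMIs. The larger lymphatic-like shares may therefore include shallow cells that other settings do not name so. For cycling-like cells equal depth left the difference, with 10.3% (8.82 to 12.0) in knockout hypoxia and 1.36% (0.857 to 2.06) in control hypoxia after cells had been thinned to 1 depth before clustering. In the main clustering 2 clusters stayed unnamed. Cluster 8, led by heat shock genes, held 6.32%, 7.20%, 8.16% and 0.590% of cells, and cluster 12, led by the replication genes Mcm5 and Hells, held 0.126%, 0.223%, 0.0680% and 3.67%.

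**Figure D4:**
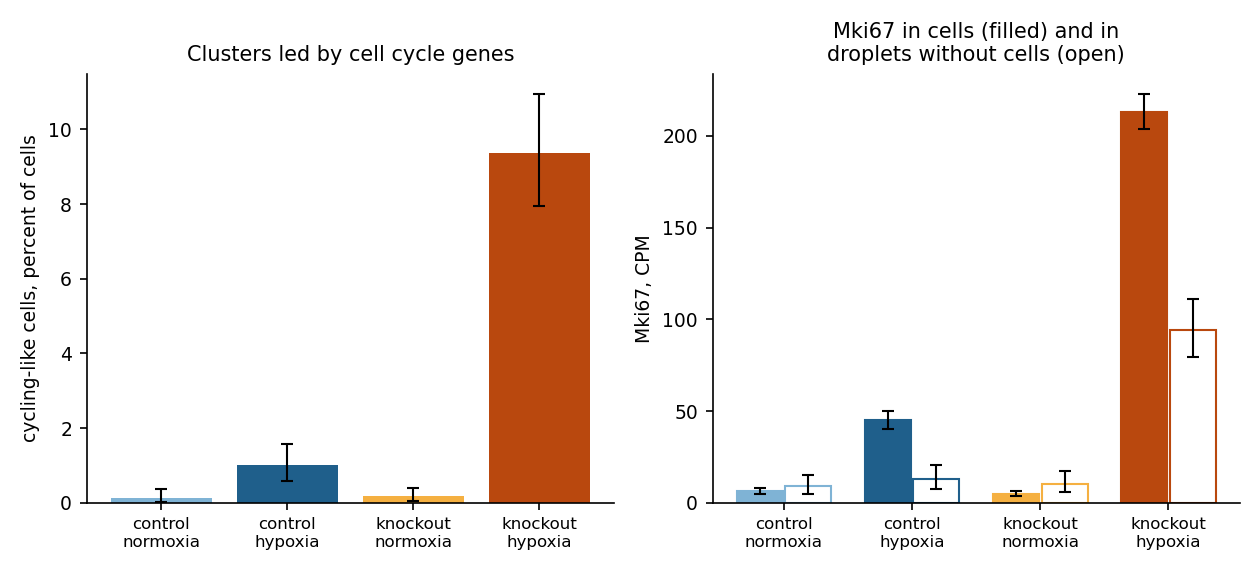
Left, percent of cells in the cycling-like cluster made without the differing genes, with exact 95% intervals; right, Mki67 CPM in cells (filled bars) and in droplets without cells (open bars) with 95% Poisson intervals, for the 4 libraries of 1 mouse each. Cycling-like cells reached 9.37% in knockout hypoxia and 1.00% in control hypoxia.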

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

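The tests of free RNA, of a whole-library shift for oxidative phosphorylation genes alone and of leaving out cluster 7 were chosen only after the results they measure had been seen. The other tests reported here were chosen before the results they measure, but those within cluster 7 after the clusters had been seen. None of the differences between the genotypes' hypoxia responses given here was tested, since each group held 1 mouse.

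In general capillary-like cells, 12 genes met the size rule in opposite directions in the hypoxia responses of control and knockout mice. The log2 response in knockout mice minus that in control mice was -7.26 for Cyp26b1, which stood at 47.1, 77.3, 1929 and 19.4 CPM. It was -3.18 for Hspa1a and -2.91 for Hspa1b, heat shock genes that were high in control hypoxia and in knockout normoxia. It was -1.92 for Ifit3b (20.2, 52.1, 25.3 and 16.5 CPM), -1.39 for Ifi44 (49.9, 84.7, 62.0 and 39.5 CPM) and -1.31 for Ifit1 (136, 224, 130.0 and 86.3 CPM), which are interferon-induced. The sulfotransferase gene Sult1a1 gave -1.97 (20.7, 36.0, 20.9 and 8.54 CPM), the ubiquitin ligase gene Mylip -1.68 (34.4, 68.9, 53.1 and 32.4 CPM) and Vsir, an immune checkpoint gene, -1.48 (64.7, 103, 112 and 63.0 CPM). Zbtb16, a zinc finger gene responsive to glucocorticoids, gave 3.03 (31.0, 9.62, 10.2 and 29.5 CPM), the endoribonuclease gene Endou 1.53 (30.3, 16.8, 29.0 and 48.3 CPM) and Mir22hg 1.49 (29.2, 18.6, 20.3 and 37.7 CPM). Genes at these low levels have wide counting intervals. All 12 met the rule in opposite directions again with free RNA subtracted, but 6 over all vascular classes and 5 with the larger pseudocount. Without cluster 7 Ifit3b, Ifi44 and Ifit1 were higher in hypoxia in both genotypes, by log2 1.48, 0.87 and 0.88 in control and 1.08, 0.78 and 0.88 in knockout mice. The knockout hypoxia cells left were 44 in cluster 6, which interferon genes led, and 12, 26, 14 and 10 in clusters 3, 4, 5 and 9. In control hypoxia they were 240 in cluster 6 and 128, 189, 97 and 257 in the others. Cluster 6 thus weighed more in knockout hypoxia, so these values cannot tell whether like cells responded alike. Nuclear oxidative phosphorylation genes as a list had a median response of -0.23 in control and 0.18 in knockout mice, each outside 95% of random lists, and these medians differed by 0.41.

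Droplets without cells, which entered the comparisons only where free RNA was subtracted as an alternative, held RNA of several blood cell types. That of B cells was above the level in control normoxia in knockout hypoxia alone, and that of erythroid cells in both hypoxia libraries. The B cell genes Igkc and Ighm reached 124 and 23.9 CPM in knockout hypoxia droplets, against 2.40 and 0.601 CPM. Hemoglobin genes Hbb-bs, Hba-a1 and Hba-a2 reached 107, 44.6 and 37.5 CPM, against 31.3, 12.6 and 9.02 CPM. Control hypoxia droplets held Hbb-bs at 75.03 CPM and the summed erythroid markers at 159 CPM, where knockout hypoxia droplets held 209 CPM and control normoxia droplets 61.3 CPM of these markers. In the cells of the knockout hypoxia library, Igkc and Ighm had 0 UMIs and Hbb-bs, Hba-a1 and Hba-a2 gave 2.09, 0.769 and 0.659 CPM. Neutrophil markers in droplets differed otherwise, at 66.1, 23.3, 125 and 80.8 CPM, and platelet markers stood at 16.2, 6.75, 29.2 and 12.9 CPM. The sort gated against CD45 and LY76, and the source of this RNA was not tested.

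Cyp26b1 in knockout normoxia was weighed first. Against a few cells as its source, the 30 cells with the most UMIs of Cyp26b1 held 5.98% of them, 2466 of 2943 cells (83.8%) held at least 1, and the lowest bound of the ratio to control normoxia over general capillary-like, arterial-like and venous-like cells was 13.2. Aerocyte-like cells were left out there after their values had been seen, since free RNA can reach their level. With them, as planned, the lowest bound was 10.7. Against free RNA as its source, the level in cells was 1.56 times (1.48 to 1.64) that in droplets without cells, and only 21 of 200 aerocyte-like cells held a UMI, against 1548 of 1703 general capillary-like cells. No test of a biological explanation is reported, and genotype, tamoxifen and the individual mouse stay open.

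The list medians of ribosomal protein and nuclear oxidative phosphorylation genes, above 0 in knockout against control hypoxia, and of interferon genes, below 0, were weighed next, although most members did not meet the size rule. Against a shift of the whole library for ribosomal genes, their median was -0.044 (-0.063 to -0.023) in venous-like cells, although 0.10 and 0.11 in aerocyte-like and arterial-like cells. For oxidative phosphorylation genes such a shift stays open, since their lowest median over these classes was 0.074 (0.0080 to 0.11), above 0 but below the 0.26 of the main class. Against unequal clusters as the cause for these 2 lists, the lower of their medians was 0.20 (0.16 to 0.29) within cluster 7, with 590 and 99 cells, where the 5072 genes compared by their higher library had a median of 0.11 and the 1898 genes with a mean of at least 100 CPM one of -0.04. For interferon genes the median within cluster 7 was -0.12 (-0.23 to 0.04), but 6 list genes led cluster 6, which that test leaves out by construction. In this class a lower response in the same cells and fewer cells of that state therefore cannot be told apart. In aerocyte-like cells, outside these clusters, the interferon median was -0.95, with 15 of 19 genes lower. It was -0.18 and -0.20 in arterial-like and venous-like cells, where most members did not meet the size rule. The genotype, tamoxifen and the individual mouse stay open and untested.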

How the results depend on the processing

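No paired analysis was possible because each group held 1 mouse, and no replicate could be left out. No comparison here rests on a test, so a count is called apart when it moved by over 1.5 times, and a value when it left its counting interval. Of the counts under the alternatives and the correlations, which were computed for only some of them, 169 stayed within these limits and 50 did not. The alternatives around clusters 6, 7 and 8, clusters without differing genes, shares under the filter of 200 genes and thinning to the lowest total were chosen after seeing the data.

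The minimum level sets how many genes are counted, by construction. In the order hypoxia in control mice, hypoxia in knockout mice, difference of responses, knockout in normoxia and knockout in hypoxia, 100 CPM gave 233, 263, 119, 32 and 50 higher and 187, 270, 150, 5 and 66 lower genes. No filter gave 1441, 1536, 2002, 1061 and 1448 higher and 2429, 2722, 2340, 676 and 1294 lower. At 5 CPM, lower genes were 987, 1495, 1109, 109 and 444, and higher genes 760, 323 and 439 in the last 3. The larger pseudocount, which shrinks ratios of low counts, gave 259, 52 and 117 higher and 294, 10 and 123 lower genes in the last 3.

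All vascular classes together gave 275, 72 and 125 higher and 349, 22 and 94 lower genes in the last 3, and 519 lower in hypoxia in knockout mice. The filter of 1000 genes and 5% mitochondrial UMIs gave 83 lower genes for the knockout in normoxia. Without cluster 7 the difference of responses had 771 higher and 950 lower genes and the knockout in hypoxia 657 lower. Cluster 7 alone gave 601 higher for the knockout in hypoxia. With or without cluster 7, the hypoxia libraries then held unequal numbers of cells, so the UMI minimum can favor genes higher in the larger library. Other causes were not tested.

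The correlation of the hypoxia responses was 0.550 by rank, 0.806 at 100 CPM, 0.689 over all vascular classes and 0.611 without cluster 7. Beside these it was computed only with TMM and median-of-ratios factors and with clusters made without the differing genes. It was above 0 in each.

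A value is called reversed when it took the other sign and was, in the main analysis, a named gene or a list median outside the middle 95% of random lists. These values reversed. Ifit3 for the knockout in hypoxia was 0.094 without cluster 6 and 0.23 without cluster 7, and the interferon median 0.015 and 0.094. Without cluster 7, cluster 6 held the most knockout hypoxia cells left in the class. The interferon median for hypoxia in control mice was -0.032 without cluster 6, which interferon genes lead. The clock median for hypoxia in knockout mice was -0.10 without cluster 7. For hypoxia in control mice, the NRF2 median was 0.028 with no filter and the vasoactive and PDGF median -0.017 over all vascular classes. The cause was not tested.

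Of 1692 list medians under alternatives, 1436 stayed within their interval, 250 moved and 6 reversed. In all 142 took the other sign, so those that lay within the random lists in the main analysis have no firm direction. Among those within the random lists, the largest such changes were the inflammation medians at 100 CPM, 0.83 and 0.65 for hypoxia in control and knockout mice in place of -0.18 and -0.11, and the interferon median for hypoxia in knockout mice without cluster 7, 0.51 in place of -0.16. Of 1847 values of named genes, 1649 stayed, 196 moved and 2 reversed, and 69 of them differed by over 1.5-fold from the main value, among them 27 over all vascular classes and 15 with the larger pseudocount. Median-of-ratios factors moved the median of all genes for hypoxia in knockout mice from -0.04 to 0.06. Of 128 class shares, 34 moved. General capillary-like cells ranged from 55.8% to 69.5%, 55.8% to 70.5%, 57.3% to 74.1% and 44.7% to 58.1%, arterial-like cells from 6.23% to 9.29%, 5.30% to 9.24%, 6.08% to 10.4% and 6.36% to 10.8% in control normoxia, control hypoxia, knockout normoxia and knockout hypoxia.

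Depth limits which genes can be compared. Of 32285 features, 6931, 7063, 6883 and 6828 reached 20 CPM and 30 UMIs in the higher library of the 4 comparisons between libraries. In simulated data at the depth of these libraries, which held counting error only, 98.5% to 100% of genes set at 2-fold were recovered.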

Other observations

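The test of free RNA for the cell cycle genes was chosen only after the result had been seen, and the other tests in this part before. The hypoxic program was not confined to general capillary-like cells. In control mice, HIF target genes had 15 of 18 higher in hypoxia in aerocyte-like cells (median log2 ratio 1.90), 12 of 17 in arterial-like cells (0.90) and 11 of 20 in venous-like cells (0.63). In knockout mice the medians were 1.43, 1.18 and 0.91 in the same order. Glycolysis medians were 1.06, 0.83 and 0.56 in control mice and 0.89, 0.83 and 0.74 in knockout mice. Matrix genes had 5 of 8 higher in aerocyte-like, 8 of 16 in arterial-like and 8 of 16 in venous-like cells of control hypoxia. Aerocyte-like cells of normoxia and hypoxia fell into separate clusters in the main clustering: cluster 2 held 222, 3, 197 and 0 cells, and cluster 13 held 4, 179, 3 and 149. This split depended on the clustering. At resolution 0.5 a single aerocyte-like cluster held 226, 182, 200 and 149 cells. Without the differing genes a single cluster held 223, 181, 198 and 149.

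Other lists differed between classes. In control hypoxia, nuclear oxidative phosphorylation genes had 19 of 78 lower in aerocyte-like cells (median -0.42) and ribosomal protein genes 6 of 82 lower in venous-like cells (-0.42). With hypoxia against normoxia, the interferon median was 0.81 in aerocyte-like cells of control mice (11 of 19 higher) and -0.43 in those of knockout mice (7 of 19 lower). In knockout hypoxia against knockout normoxia the antigen presentation median was -0.49 in arterial-like (6 of 16 lower) and -0.61 in venous-like cells (8 of 16 lower). In knockout against control normoxia, NFAT5 osmotic targets had medians of 0.55, 0.29 and 0.23 in aerocyte-like, arterial-like and venous-like cells. In knockout against control hypoxia, interferon medians were -0.95 (15 of 19 lower), -0.18 and -0.20 and BMP and TGF-beta medians -0.15, -0.27 and -0.36 in that order. Hypoxia gave 659 higher and 827 lower genes in aerocyte-like cells of control mice, 452 and 456 in arterial-like and 665 and 466 in venous-like cells. Knockout against control gave 291 higher and 179 lower genes in normoxia in aerocyte-like, 410 and 199 in arterial-like and 245 and 121 in venous-like cells. These classes are smaller than the main one, so low counts weigh more in their numbers of genes.

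Pdpn, a negative gate of the sort, was at 0.224, 0.876, 0.722 and 5.71 CPM over all cells, and lymphatic-like cells were 1.37% to 5.57% of the knockout hypoxia library, depending on the filter and clustering. The larger of these shares may include shallow cells, since the main lymphatic-like cluster had a median of 1605 UMIs, against 6518 UMIs at resolutions 0.5 and 2.0.

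Cell cycle genes were higher over all cells in knockout hypoxia than in control hypoxia, and against free RNA as the cause, Mki67 in cells of the knockout hypoxia library was 2.26 times (1.91 to 2.69) its level in droplets without cells. Against deeper cells as the whole cause, the list had a median log2 ratio of 1.21 (1.01 to 1.49, 14 members) among cells with 2296 to 4794 UMIs, 508 in knockout and 896 in control hypoxia, whose median depths were 3624 and 3350 UMIs. After cells had been thinned to 1 depth before clustering, cycling-like cells were 10.3% (8.82 to 12.0) in knockout and 1.36% (0.857 to 2.06) in control hypoxia, against 8.78% and 1.23% at full depth. Thinned and full-depth shares are not comparable with each other. Thinning left out cells below that depth. At full depth cluster 12, led by replication genes, was counted apart, with 56 knockout and 4 control hypoxia cells. Against dividing cells of another type, the 8 pan-endothelial genes stood in the 190 cells of the cell cycle clusters at a median of 79.4% of their level in the other 1336 cells. The lowest and highest single genes were at 61.5% and 114%. More endothelial division in this 1 mouse may therefore lie behind it, while the genotype, tamoxifen, the individual mouse and the sort stay open and untested.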
